A study of Homo sapiens and Rattus norvegicus with 78 samples.

How the data were processed

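RNA sequencing of poly-A mRNA was available for 78 libraries in 39 groups of 2 replicate libraries, A and B. The cells were human neural stem cells derived from the H9 embryonic stem cell line (NSC), SK-N-SH human neuroblastoma cells (SK) and PC12 rat pheochromocytoma cells. Each cell model had a control group with 0.1% DMSO. The other groups received 1 compound each, neonicotinoid insecticides and organophosphate esters at 1 µM and antioxidants at 100 nM, and the labels give 8 days of treatment. NSC had 20 compounds, and SK and PC12 had 8 of these.

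The values were inherited as follows. The deposited tables hold expected counts per gene with 2 decimals, per the file headers a read count, for 18997 human genes and 17344 rat genes, not scaled to a common total. The authors' notes name the genome builds GRCh38.p13 and Rnor_6.0 and no aligner or counting tool. The rat table also holds the authors' log2 fold changes against the control. Beside them stand q values which, per the file headers, came from DESeq2, with no version or design stated. No mitochondrially encoded gene was listed, and coordinates came with the rat genes.

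Counts were rounded to whole numbers. Genes were kept with filterByExpr by group and libraries were scaled by TMM in edgeR 4.0.16 (R 4.3.3), which left 14954 genes in NSC, 15058 in SK and 12420 in PC12. All groups of a cell model shared 1 quasi-likelihood fit (glmQLFit, glmQLFTest), since 2 libraries per group give little information on the spread alone. Contrasts were each compound against the control, 16 pairs of related compounds in NSC and 4 pairs each in SK and PC12, and an F test over all groups. A joint fit of NSC and SK over 15990 genes tested the effect in NSC minus the effect in SK for the 8 shared compounds. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, two-sided. Genes at an unadjusted p under 0.05 are counted too. With no difference at all, a share of 0.05 of the genes tested would fall there. Standard errors (SE) belong to the fitted log2 fold change, and levels are counts scaled to library size (CPM, from cpm in edgeR) as mean ± SD over 2 libraries.

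Gene lists were fixed before the data were examined. They covered neural progenitor, neuronal, glial, mesenchymal and pluripotency markers, catecholamine, cholinergic and synaptic genes, AHR, PXR and CAR, NRF2 and p53 targets, unfolded protein and integrated stress, heat shock, cell cycle, replication, sterol, lipid, hypoxia, oxidative phosphorylation, ribosomal, immediate early, signalling, regional, interferon and histone genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over all lists and comparisons of a model. Camera with an estimated correlation and fry were run beside it. Lists with fewer than 5 tested genes were left out: mitochondrial mRNAs, nuclear-retained RNAs and metallothioneins in every model, and in PC12 also the glial, AHR, PXR and CAR, regional and histone lists.

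The genes named were chosen by a rule fixed before the data were examined. It took genes past the threshold with a mean of at least 1 CPM over both groups and both treated libraries on the same side of both control libraries. Of these it named the 3 largest rises and falls per comparison, or 12 of each for the comparison with the most calls in a model. It added the 10 genes called in the most comparisons, the largest rise and fall per pair of related compounds, up to 4 members per list with the smallest p adjusted over the list alone, and 12 fixed genes. All genes whose effect differed between NSC and SK are named, a choice made after their number was seen.

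Resemblance between models and within chemical classes was tested one-sided by permuting compound or class labels, exactly for the models and for classes in SK and PC12, and with 100000 draws for classes in NSC. The permutation p-values were adjusted over the 3 tests of each family. The procedure was tested on simulated counts with known changes at the real depth. At a simulated 2-fold change it recovered 77.6% of changed genes in NSC, 71.6% in SK and 83.6% in PC12. It recovered 61.2% for the difference between NSC and SK. At 1.5-fold these shares were 71.6%, 41.8%, 38.8% and 26.9%. In the same simulated comparisons 7 unchanged genes were called in NSC, 10 in SK, 6 in PC12 and 0 for the difference. In a comparison with no changed gene, 0 were called in NSC, 0 in SK and 2 in PC12.

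Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors in the same fit, no filter on low counts, the replicate letter as a block, 2 groups fitted alone, and leaving out each library in turn. Where that left 1 library in a group, it was assumed to vary like the other groups. Other alternatives were added after the data were seen: a term for sets of libraries read from marker transcripts, each compound against the mean of the other treated groups, removal of each library's trend over transcript length, and leaving out 8 NSC libraries with transcripts of other tissues. Transcript lengths came from GENCODE 29. The closing section gives their effect. No library was excluded from the main fits. Tables were handled with data.table (version 1.17.8) and pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.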

Results

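The 78 libraries profiled mRNA in 3 neural cell models after exposure to insecticides, flame retardants and plasticizers, and antioxidants. Neural stem cells (NSC) had 21 groups, a DMSO control and 20 compounds, and SK-N-SH neuroblastoma (SK) and PC12 pheochromocytoma cells had 9 groups each. Each group had 2 libraries, so n = 2 stands behind every mean below. Total counts per library were 19419856 to 20251963 in NSC, 13850353 to 18896444 in SK and 7931620 to 8339990 in PC12. The 95% interval of a log2 fold change had a median width of ±0.22 in NSC, ±0.33 in SK and ±0.28 in PC12. Compounds carry the labels' abbreviations, such as ACE for acetamiprid, IMI for imidacloprid, TDCIPP, TnBP, TCEP, TEP and TPHP for organophosphate esters, and BHT and BHA for phenolic antioxidants.

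TDCIPP, a chlorinated organophosphate flame retardant, had 421 genes higher and 216 lower than the control in NSC (edgeR). Its A library and control A were in different library sets, so a difference between sets does not cancel in this contrast. With the library set as a term 566 genes were called (381 higher, 185 lower), and 468 of the 637 were called in both fits. The largest rise was in IL7R, the interleukin-7 receptor (Entrez 3575), at 2.09 ± 0.22 CPM against 0.325 ± 0.03 CPM, a log2 fold change of 2.66 ± 0.61 (SE, adjusted p = 0.0108). CP, which encodes the ferroxidase ceruloplasmin (Entrez 1356), stood at 24.6 ± 0.64 CPM against 7.14 ± 0.97 CPM (log2 1.79 ± 0.36, adjusted p = 0.00371). Other named rises were the integrin ITGB3 (log2 1.76), the protease PAPPA (1.65), the procollagen protease ADAMTS14 (1.61), SMOC2 (1.51), VASN (1.37) and the adhesion receptor ADGRL4 (1.62), and UBD (1.81), C7orf57 (1.46), FMN1 (1.37) and LAMP3 (1.37) completed the 12 largest rises. The largest fall was in EOMES, a T-box factor of neuronal precursors (Entrez 8320), from 4.45 ± 0.44 to 1.1 ± 0.33 CPM (log2 −2.02 ± 0.43, adjusted p = 0.00624). The transcription factors DMRTA2 (−1.56), NR5A2 (−1.55), NHLH1 (−1.22), NEUROD1 (−1.16) and PRRX1 (−1.13) fell. So did the signalling genes BMP3 (−1.40) and TRH (−1.36) and the nicotinic receptor subunit CHRNA3 (−1.15). HSD11B2 (−1.42) and COL20A1 (−1.20) also fell.

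The neuronal differentiation list fell under TDCIPP, with 9 of its 24 measured members lower and 1 higher over all genes tested, and 16 lower and 2 higher adjusted over the list alone (median log2 −0.49, camera adjusted p = 9.14e-09). Members were ELAVL3 (log2 −0.49 ± 0.09), INA (−0.60 ± 0.12) and NHLH1 (−1.22 ± 0.27), while NEFL, a neurofilament gene, rose (0.38 ± 0.08). This call had adjusted p = 0.159 with an estimated correlation. The list of the unfolded protein and integrated stress response rose with 7 of 21 members higher by both counts and none lower, among them HERPUD1 (0.43 ± 0.07), CHAC1 (0.55 ± 0.13) and the chaperones PDIA4 (0.34 ± 0.08) and HYOU1 (0.28 ± 0.07). Its median was 0.22 (adjusted p = 7.56e-08, adjusted p = 0.152 with an estimated correlation). NRF2 targets had 4 of 18 members higher, and 7 adjusted over the list alone (median 0.22, adjusted p = 7.64e-07, adjusted p = 0.152 with an estimated correlation), among them NQO1 (0.44 ± 0.10) and the cystine transporter SLC7A11 (0.61 ± 0.16). The p53 targets had 3 of 18 higher, and 9 adjusted over the list alone (median 0.21, adjusted p = 4.21e-07, adjusted p = 0.152 with an estimated correlation), including CDKN1A (0.44 ± 0.10) and TNFRSF10B (0.31 ± 0.07).

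Cholinergic genes fell with 2 of 13 members lower, the acetylcholine transporter SLC18A3 (−0.53 ± 0.11) and CHRNA3, and 5 lower adjusted over the list alone (median −0.20, adjusted p = 0.00176, adjusted p = 0.0856 with an estimated correlation). Forebrain regulators of the regional list were lower: NKX2-1 (−0.59 ± 0.12), EMX2 (−0.86 ± 0.19) and OTX2 (−0.48 ± 0.11), 3 of 12 members, and adjusted over the list alone 6 lower and 2 higher (median −0.32, adjusted p = 0.00309, adjusted p = 0.223 with an estimated correlation). Fatty acid and lipid genes rose with 3 of 17 members higher, and 5 adjusted over the list alone (median 0.18, adjusted p = 0.000467, adjusted p = 0.188 with an estimated correlation). Among them were the desaturase FADS2 (0.29 ± 0.05) and its regulator SREBF1 (0.41 ± 0.09). The mesenchymal list rose with 6 of 18 members higher, such as SPARC (0.47 ± 0.07) and COL1A2 (0.74 ± 0.15), and 1 lower, PRRX1. Adjusted over the list alone, 7 were higher and 1 lower (median 0.37, adjusted p = 0.00044, adjusted p = 0.227 with an estimated correlation). Interferon and inflammatory genes rose through 4 of 18 members by both counts, CCL2 (1.14 ± 0.19), ICAM1 (1.18 ± 0.23), IFITM1 (0.70 ± 0.15) and IFITM3 (0.58 ± 0.13), with a median of 0.23 (adjusted p = 0.000104, adjusted p = 0.197 with an estimated correlation). The TDCIPP calls depended on single libraries: 241 genes passed without TDCIPP A, 145 without TDCIPP B, 313 without control A and 94 without control B. All 32 named genes kept their direction in these fits, and without control B 4 of them stayed past the threshold.

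IMZ and CYC, both listed with the neonicotinoids, changed 592 genes (394 higher, 198 lower) and 317 genes (217 higher, 100 lower) in NSC. Of these, 163 genes were higher and 68 lower under both, and no gene was called in opposite directions. SPOCD1 (Entrez 90853) and ANKRD1 (Entrez 27063) rose under both: ANKRD1 went from 3.13 ± 0.78 CPM to 19.3 ± 1.38 under IMZ (log2 2.62 ± 0.48, adjusted p = 0.00266) and 12.5 ± 1.78 under CYC (log2 2.00 ± 0.49, adjusted p = 0.0272). SPOCD1 rose by log2 2.46 ± 0.49 and 2.37 ± 0.50. The other largest rises were LOXL4, a lysyl oxidase, under IMZ (2.48 ± 0.44) and SERPINB2, an inhibitor of plasminogen activators, under CYC (2.64 ± 0.40). Falls under IMZ were led by SYT2 (−1.43 ± 0.33), a synaptotagmin, the proneural factor NEUROG2 (−1.37 ± 0.39) and RGS7 (−1.18 ± 0.34). Under CYC they were DHRS3 (−1.28 ± 0.34), TLL1 (−1.27 ± 0.29) and SOX3 (−1.22 ± 0.16), a transcription factor of neural progenitors.

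Immediate early genes rose under both compounds, with 7 of 17 members higher each and 11 (IMZ) and 10 (CYC) adjusted over the list alone. IER3 (1.11 ± 0.16 and 0.89 ± 0.16), JUNB (0.93 ± 0.20 and 0.86 ± 0.20) and SPRY2 (0.52 ± 0.13 and 0.55 ± 0.13) are examples. The medians were 0.52 and 0.56 (adjusted p = 2.82e-09 and 7.71e-10, for both adjusted p = 0.0856 with an estimated correlation). Neural progenitor markers fell, with 4 of 18 lower under IMZ and 3 under CYC, and adjusted over the list alone 9 lower and 1 higher under IMZ and 5 lower under CYC. SOX3, MSI1 (−0.33 ± 0.07 and −0.28 ± 0.07) and the Notch target HES5 (−1.01 ± 0.24 and −1.03 ± 0.24) fell under both. The adjusted p was 0.00107 for IMZ and 0.000248 for CYC, and these calls had adjusted p = 0.216 and 0.188 with an estimated correlation. The neuronal differentiation list fell under IMZ (median −0.54, adjusted p = 2.19e-05, adjusted p = 0.241 with an estimated correlation) and CYC (median −0.22, adjusted p = 0.00361, adjusted p = 0.419 with an estimated correlation). Over all genes it held 5 lower and 2 higher under IMZ and 2 lower and 2 higher under CYC, and adjusted over the list alone 14 lower and 2 higher, and 5 lower and 2 higher. The Notch ligand DLL1 (−0.73 ± 0.16 and −0.61 ± 0.16) fell, while the neurofilament genes NEFM (0.80 ± 0.13 and 0.83 ± 0.13) and NEFL (0.45 ± 0.08 and 0.42 ± 0.08) rose. Without control B the CYC call was lost (adjusted p = 0.0757).

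NQO1 led the NRF2 targets under IMZ (0.56 ± 0.10) and CYC (0.54 ± 0.10). The list had 2 and 1 of 18 members higher, and 3 and 1 adjusted over the list alone (adjusted p = 1.36e-05 and 0.000275, adjusted p = 0.152 and 0.188 with an estimated correlation). The p53 targets rose with CDKN1A (0.56 ± 0.10 and 0.58 ± 0.10) and GDF15 (1.13 ± 0.27 and 1.26 ± 0.26), 4 and 3 of 18 higher and 1 lower under IMZ, and 8 and 6 higher with 1 lower each adjusted over the list alone. Their adjusted p was 1.36e-05 and 1.52e-05, and both had adjusted p = 0.188 with an estimated correlation. Glucose transport genes rose under IMZ in the hypoxia and glycolysis list, SLC2A3 (0.71 ± 0.11) and SLC2A1 (0.37 ± 0.07), with 4 of 18 members higher, and 6 higher and 1 lower adjusted over the list alone (median 0.05, adjusted p = 0.0107, adjusted p = 0.152 with an estimated correlation). The 8 NSC libraries with transcripts of other tissues include control A and the A libraries of IMZ and CYC. With these left out, 8 genes passed for IMZ, 12 for CYC and 341 for TDCIPP. Against the mean of the other treated groups, with no control library, 34 genes passed for IMZ, 83 for CYC and 785 for TDCIPP, and 33, 71 and 397 of these were also called against the control. The library set does not cancel there, as 13 treated A libraries, TDCIPP A among them, were in another set than IMZ A and CYC A. Left out singly, the libraries gave 143 genes for IMZ without IMZ A, 213 without IMZ B, 223 without control A and 84 without control B. For CYC they gave 23 without CYC A, 197 without CYC B, 105 without control A and 51 without control B.

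DTBP, grouped here with the antioxidants at 100 nM, had 235 genes higher and 288 lower in NSC, and its library B stood apart from the other NSC B libraries. As for TDCIPP, its A library and control A were in different library sets, so a difference between sets does not cancel. With the library set as a term 1402 genes were called (680 higher, 722 lower), and 518 of the 523 were called in both fits. Without DTBP B 3 genes passed, without DTBP A 3177, and without control A none did. ANKRD1 (2.10 ± 0.49), SPOCD1 (2.01 ± 0.51) and SERPINB2 (1.93 ± 0.42) were the largest rises, and SYT2 (−1.39 ± 0.33), TLL1 (−1.16 ± 0.29) and the bombesin-type receptor BRS3 (−1.13 ± 0.31) the largest falls. The p53 targets rose with 5 of 18 members higher and 12 adjusted over the list alone, such as CDKN1A (0.56 ± 0.10), with a median of 0.27 (adjusted p = 3.17e-07, adjusted p = 0.152 with an estimated correlation). Ribosomal and oxidative phosphorylation lists were higher in library B, by median log2 0.28 and 0.27 from the other NSC B libraries, and their calls for DTBP turned direction without DTBP B.

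The other NSC compounds had fewer calls. AO168 had 49 genes (23 higher, 26 lower), TPHP 37 (18 and 19), ACE 17 (11 and 6) and AO2246 10 (1 and 9). SERPINB2 rose under AO168 (2.09 ± 0.42), TPHP (2.09 ± 0.42) and ACE (2.36 ± 0.41). COL13A1, a transmembrane collagen, rose under these and under AO2246 (1.14 ± 0.21). ICAM1 under AO168 (1.17 ± 0.23), IL4R under TPHP (0.94 ± 0.21) and CCL2 under ACE (0.96 ± 0.19) were the remaining named rises. The largest falls were TLL1 (−1.66 ± 0.30) under AO168, DHRS3 (−1.89 ± 0.36), a retinal reductase, under TPHP, OLIG1 (−1.26 ± 0.22), a glial lineage factor, under ACE and SOX3 (−0.79 ± 0.16) under AO2246. CDH20 (−0.84) and SOX3 (−0.74) under AO168, CHST9 (−1.26) and SOX3 (−1.10) under TPHP, SH2D3C (−0.69) and CNR1 (−0.48) under ACE, and PI15 (−0.64) and VSTM4 (−0.55) under AO2246 also fell. CHODL was the single edgeR call of IMI (0.61 ± 0.10), TCEP (0.63 ± 0.10) and TnBP (0.73 ± 0.10). The A libraries of AO168, TPHP and AO2246 were in another library set than control A, so a difference between sets does not cancel for them. The counts above depended on the fit. With the library set as a term they were 194 for AO168, 65 for TPHP, 88 for ACE, 139 for AO2246, 17 for IMI, 34 for TCEP and 20 for TnBP, and DESeq2 called 108, 64, 70, 61, 16, 38 and 20. Single libraries changed them as well. AO168 had 0 without AO168 A, 2 without AO168 B, 0 without control A and 4 without control B. TPHP had 3 without TPHP A, 2 without TPHP B, 2 without control A and 11 without control B. ACE had 0 without ACE A, 172 without ACE B and 0 without either control library. AO2246 had 0 without AO2246 A, 1 without AO2246 B, 0 without control A and 3 without control B. IMI and TCEP had 0 without any 1 of their own or the control libraries, and TnBP 0 without TnBP B and 2 without control B.

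For 9 compounds edgeR called 0 genes in NSC. All but TEP had their A library in another library set than control A, so a difference between sets does not cancel. Genes at an unadjusted p under 0.05 numbered 687 for BHA, 534 for BHT, 724 for BHT_CHO, 794 for BHT_COOH, 620 for BHT_Q, 977 for BHT_ql, 866 for DG, 457 for TBHQ and 1009 for TEP. The shares of genes tested ran from 3.06% (TBHQ) to 6.75% (TEP), on both sides of the 0.05 that no difference would give. DESeq2 called 1 gene for BHT_Q, 3 for DG, 2 for TEP and 0 for the others, and with the library set as a term edgeR called 24 for DG, 1 for BHT_COOH and 0 for the others. Any difference among the 21 groups was found for 340 genes (F test), 185 without TDCIPP A, 195 without TDCIPP B and 1061 without DTBP A.

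A small set of genes recurred across compounds in NSC, all measured against the same 2 control libraries. CHODL was called in 9 comparisons, COL13A1 in 8, CCL2, SOX3 and C21orf62 in 7, PI15, UNC5C, SERPINB2 and SLC2A3 in 6 and CDKN2B in 5. CHODL, a C-type lectin of motor neurons, stood at 27.0 ± 0.71 CPM in the control and was higher under each of the 20 compounds, by log2 0.27 to 1.08, the largest under TDCIPP (56.9 ± 1.61 CPM). SOX3 was lower under each of the 20, by log2 −0.39 to −1.22. The chemokine gene CCL2 was higher under each, by 0.33 to 1.60, as were COL13A1 and the netrin receptor gene UNC5C. Of the 14954 genes tested, 13505 were called in no comparison and 1009 in 1 alone.

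**Figure D1:**
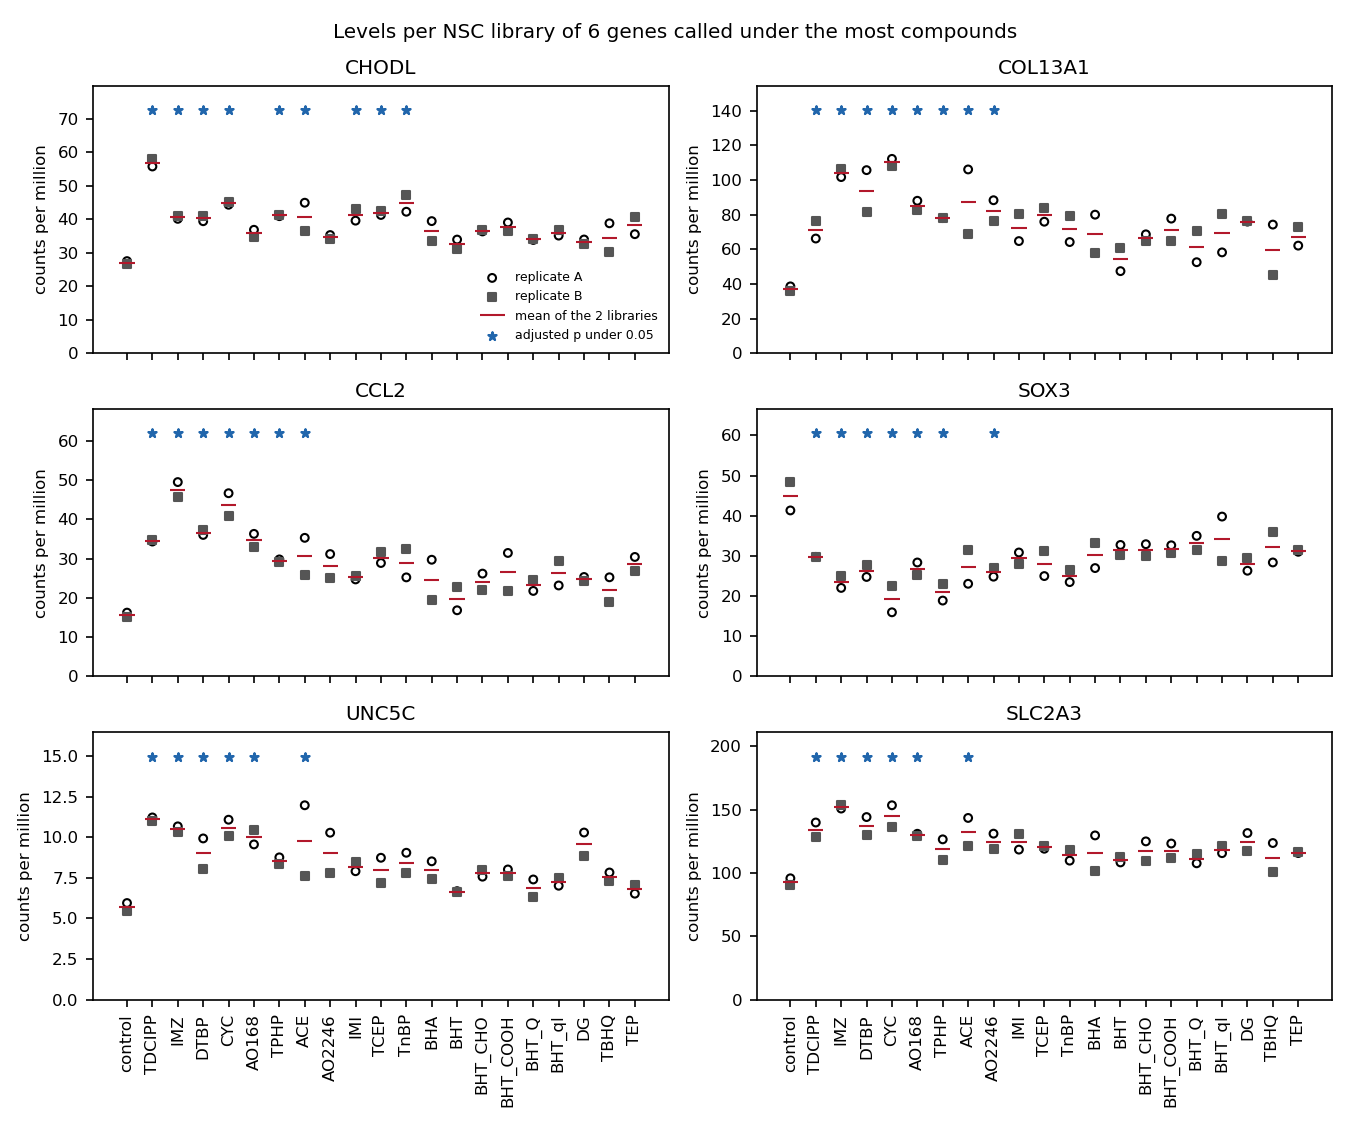
Levels of 6 recurrent genes in NSC (vertical axis, CPM) for the control and the 20 compounds (horizontal axis), with circles for library A, squares for library B, a red line for the mean of 2 libraries and a star at adjusted p under 0.05. CHODL is above the control mean of 27.0 CPM under each compound, and SOX3 is below its control mean of 44.9 CPM under each.

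Across all compounds, 219 of 520 list tests passed in NSC, 151 higher and 68 lower, and none passed with an estimated correlation, where the adjusted p ran from 0.0856 upward. The p53 targets passed as higher under all 20 compounds (median log2 0.06 to 0.27), immediate early and mesenchymal genes under 19 and interferon genes under 17. NRF2 targets passed as higher under 15, DNA replication genes under 13, heat shock proteins under 12 and hypoxia genes under 11. Neuronal differentiation and histone genes passed as lower under 15 each, and progenitor and regional genes under 9 each. The medians themselves were above 0 under all 20 compounds for immediate early (0.12 to 0.59), mesenchymal (0.04 to 0.41), interferon (0.01 to 0.27), NRF2 (0.02 to 0.22) and hypoxia genes (0.003 to 0.17). They were below 0 under all 20 for neuronal (−0.54 to −0.04) and histone genes (−0.54 to −0.10). Replication, heat shock, progenitor and regional medians lay on both sides of 0. Many of these calls rested on 1 control library. Without control A 9 of the 12 heat shock, 8 of the 13 DNA replication, 8 of the 15 NRF2 and 8 of the 17 interferon calls were lost. Without control B 14 of the 15 histone, 6 of the 15 neuronal, 6 of the 9 regional and 4 of the 9 progenitor calls were lost. These comparisons share the control libraries, and against the mean of the other treated groups 57 of the 219 passed in the same direction. For TDCIPP these included neuronal differentiation (adjusted p = 1.8e-05), the unfolded protein response (3.07e-07), NRF2 targets (2e-04) and fatty acid genes (7.29e-05), and for IMZ and CYC immediate early genes (1.47e-05 and 0.000229) and progenitor markers (0.00182 and 0.0011). The library set does not cancel in these contrasts. IMZ A and CYC A were in a set of 8 A libraries, and TDCIPP A in another of 13. So these values do not part the compound from the library set. Glial, pluripotency, catecholamine, PXR and CAR, and WNT, BMP, Hedgehog and Notch lists had 0 calls by camera in NSC, at a smallest adjusted p of 0.0558.

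**Figure D2:**
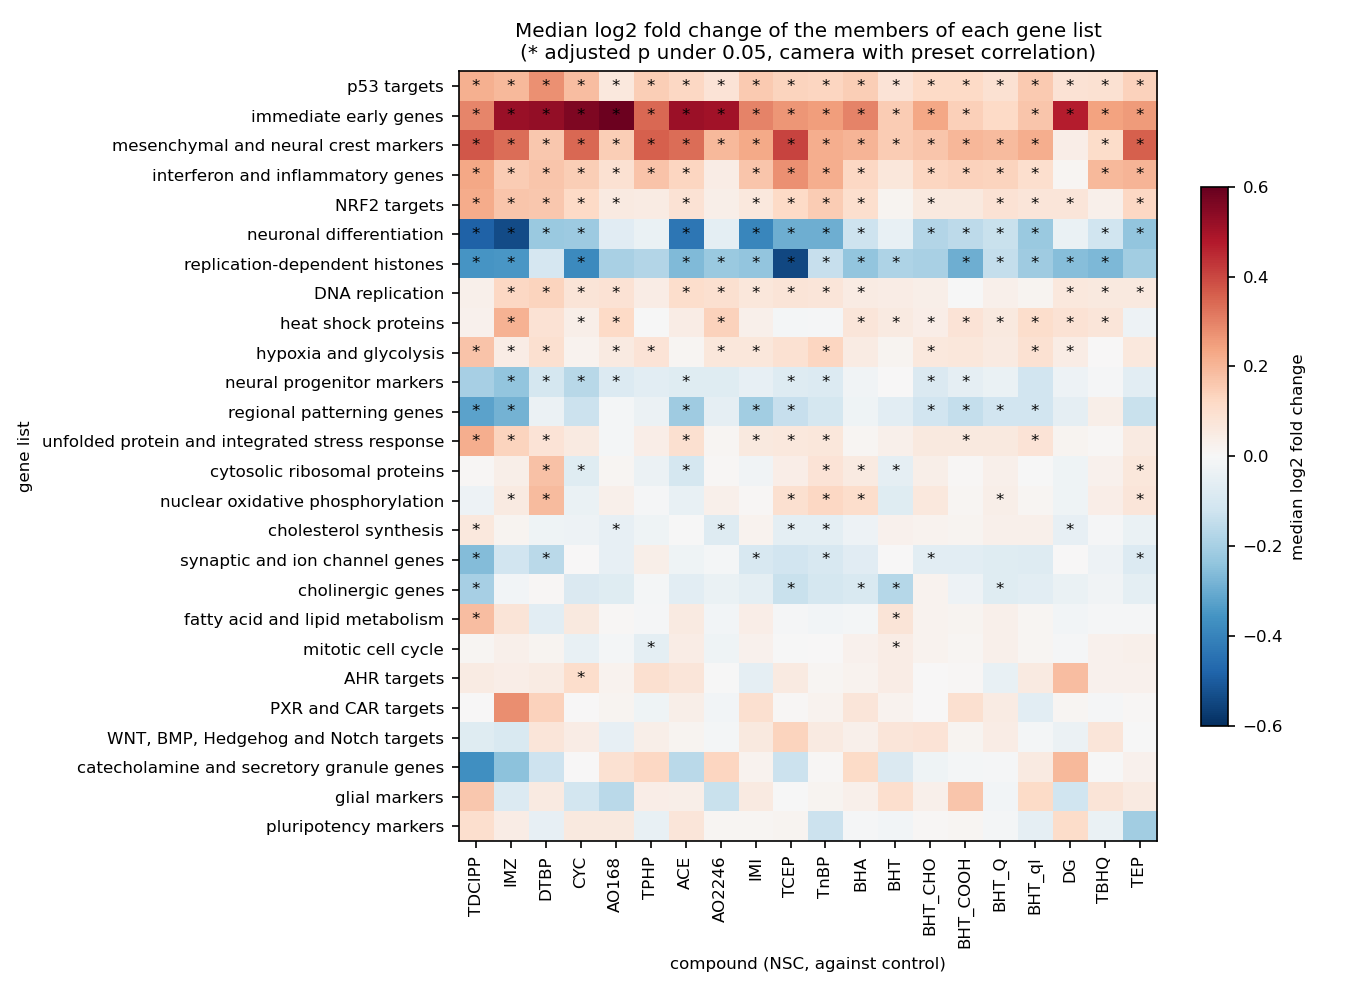
Median log2 fold change against the control of 26 gene lists (rows) for 20 compounds (columns) in NSC, with red higher, blue lower and a star at camera adjusted p under 0.05. The p53 row has a star in all 20 columns. The neuronal differentiation row is lower in all 20 and has a star in 15.

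Of the fixed genes, NQO1 passed in 4 of the 20 NSC comparisons (log2 0.13 to 0.56, control 78.5 ± 0.82 CPM), DCX, a microtubule protein of young neurons, in 2 (−0.63 to −0.05) and SOX2 in 1 (−0.24 to 0.03). CYP1A1 (−1.22 to 0.42), CYP1B1 (0.04 to 0.90), HMOX1 (−0.28 to 0.23), CHRNA7 (−0.30 to 0.19), CHRNA4 (−0.82 to 0.46), ACHE (−0.04 to 0.33), MKI67 (−0.34 to 0.18), PAX6 (−0.38 to 0.10) and TUBB3 (−0.15 to 0.08) passed in none by edgeR.

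Related compounds at the same dose were compared directly, without the control. TDCIPP against TnBP, a chlorinated against a butyl ester, gave 146 genes higher and 44 lower, with FRMD3 the largest rise (1.14 ± 0.28) and ARHGAP20 the largest fall (−1.29 ± 0.28). TCEP against TDCIPP, both chlorinated, gave 28 higher and 88 lower, with CPNE5 (1.14 ± 0.26) and BBOX1 (−0.97 ± 0.24) at the ends. In both pairs TDCIPP A was in another library set than the A library it was compared with. With the library set as a term 172 of the 190 genes of the first pair and 108 of the 116 of the second were called too. CYC against IMI gave 5 higher and 5 lower, among them DKK1, a WNT antagonist (1.31 ± 0.24), and PI15 (−0.62 ± 0.12). AO2246 against BHT gave 1 higher, the spectrin gene SPTBN5 (1.31 ± 0.25), and 6 lower, led by PALMD (−0.53 ± 0.10). TDCIPP against TnBP had 49 genes without TDCIPP A, 86 without TDCIPP B and 48 without TnBP A, and TCEP against TDCIPP 29 without either TCEP A or TDCIPP A and 38 without TDCIPP B, 67 without TCEP B and 176 without DTBP B. CYC against IMI had 0 without CYC A or IMI B and 1 without IMI A, and AO2246 against BHT 0 without AO2246 A or BHT A and 2 without AO2246 B.

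The other 12 pairs in NSC gave 0 genes with edgeR. They were pairs of neonicotinoids or organophosphate esters (ACE against IMI, 297 genes at an unadjusted p under 0.05, IMZ against IMI 1054, IMZ against CYC 623, TnBP against TEP 225, TCEP against TEP 247, TPHP against TnBP 607) and antioxidant pairs (BHT_Q, BHT_ql, BHT_COOH, BHT_CHO and BHA against BHT with 287, 467, 495, 587 and 509, and TBHQ against BHA 254). The shares of genes tested ran from 1.5% (TnBP against TEP) to 7.05% (IMZ against IMI). All but the last lay below the share of 0.05 that no difference would give. DESeq2 called 12 genes for IMZ against IMI and 0 for the others. For IMZ against IMI edgeR called 27 with the library set as a term and 2 without IMZ B. The 95% interval of the difference lay within ±1 log2 for 86.1% to 87.6% of genes in these pairs, so smaller differences stay open.

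In SK, edgeR called 0 genes in each of the 8 comparisons with the control and 0 among all groups. At an unadjusted p under 0.05 there were 3850 genes for BHT, 520 for AO2246, 310 for DG, 269 for TDCIPP, 181 for BHT_Q, 170 for TnBP, 161 for CYC and 149 for IMZ, and 548 in the F test. Apart from BHT at 25.6%, the shares of genes tested ran from 0.99% (IMZ) to 3.45% (AO2246), with 3.64% in the F test. These lie below the share of 0.05 that no difference would give. They show no excess of small p-values, and the test may have been stricter than its nominal level. DESeq2 called 155 for BHT, 0 for IMZ, 1 to 3 for each other compound and 30 in its test over all groups. BHT library B stood apart: without BHT A 8357 genes passed for BHT, and without BHT B 0 did. The test over all groups gave 6134 genes without BHT A and 2 without BHT B. AO2246 had 2 genes without AO2246 B and 1 without BHT B, and TDCIPP 1 without BHT B. Ribosomal protein genes (24 of 24 higher adjusted over the list alone, median 0.77, adjusted p = 8.1e-08) and oxidative phosphorylation genes (17 of 20, median 0.90, adjusted p = 4.75e-07) were higher under BHT. In library B alone they stood 1.22 and 1.40 above the other libraries, and without it both had adjusted p = 0.69. Both had adjusted p = 0.947 with an estimated correlation.

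Among the other SK lists, hypoxia and glycolysis genes were lower under TDCIPP (median −0.23, adjusted p = 1.13e-13) and DG (median −0.24, adjusted p = 1.1e-10), where PDK1 stood at log2 −0.36 ± 0.13 and −0.43 ± 0.13 and no member passed adjusted over the list alone. The list was also lower under AO2246, CYC and TnBP, which single libraries ended (adjusted p = 0.187 without AO2246 B, 0.917 without CYC A, 0.947 without control B), and these had adjusted p = 0.711, 0.947 and 0.947 with an estimated correlation. Mesenchymal markers were lower under IMZ (median −0.32, adjusted p = 8.57e-09) and DG (median −0.32, adjusted p = 4.03e-07), with LUM at −0.56 ± 0.18 under IMZ. The calls of TDCIPP, DG and IMZ here had adjusted p = 0.687 with an estimated correlation. Related pairs gave 0 genes with edgeR in SK. For IMZ against CYC, TDCIPP against TnBP, BHT_Q against BHT and AO2246 against BHT, 143, 142, 3723 and 5657 genes stood at an unadjusted p under 0.05. In this order they made up 0.95%, 0.94%, 24.7% and 37.6% of the genes tested. DESeq2 called 0, 0, 108 and 2977. Without BHT A edgeR called 8260 for BHT_Q and 8895 for AO2246 against BHT, and for the latter 8 without AO2246 B and 2 without BHT B.

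In PC12, edgeR also called 0 genes in each comparison and 0 among all groups, with 560 (DG) to 1089 (BHT) genes at an unadjusted p under 0.05 and 698 in the F test. DESeq2 called 0 genes for BHT_Q and TnBP, 1 to 3 for each other compound and 23 over all groups. Without control B edgeR called 2 (BHT, DG) to 7 (CYC) genes per compound, and 1 over all groups. Without their own library B, AO2246, BHT_Q and CYC had 1 gene each. The mitotic list was lower under all 8 compounds, by a median log2 of −0.10 to −0.19. These 8 comparisons share the same 2 control libraries, so they are not independent. Against the mean of the other treated groups, where an effect common to all compounds cancels as well, the list had 0 calls. Under CYC, 5 of 20 members were lower adjusted over the list alone and 0 over all genes, among them Top2a, a topoisomerase of dividing cells (262 ± 10.2 CPM against 336.6 in the control, log2 −0.36 ± 0.07), Bub1 (−0.28 ± 0.07) and Mki67 (−0.44 ± 0.13). Under BHT the same counts were 5 and 0, under IMZ 4 and 0 and under AO2246 3 and 0. The adjusted p was 1.01e-05 for CYC, AO2246 and TDCIPP and 1.49e-05 for BHT, and these had adjusted p = 0.0848 with an estimated correlation. They passed without any 1 of their own or the control libraries. Those of BHT_Q, DG, IMZ and TnBP had adjusted p = 0.118, 0.118, 0.118 and 0.203 with an estimated correlation and were lost without control B (adjusted p = 0.064, 0.0936, 0.076 and 0.182). BHT_Q was lost without BHT_Q B (adjusted p = 0.132) and TnBP without TnBP A (adjusted p = 0.123) as well. DNA replication genes were lower under TDCIPP (median −0.13, adjusted p = 0.000416), with Ccne2 at −0.31 ± 0.08, and under CYC, AO2246, IMZ and DG. In this order the 5 calls had adjusted p = 0.118, 0.118, 0.371, 0.371 and 0.383 with an estimated correlation. Those of AO2246, IMZ and DG were lost without control A (adjusted p = 0.278, 0.252 and 0.361) and that of CYC without CYC A (adjusted p = 0.112). Of the mitotic and DNA replication calls, IMZ also lost 1 without IMZ B, and DG lost 1 or more without DG B. Related pairs gave 0 genes with edgeR (442 for IMZ against CYC, 605 for TDCIPP against TnBP, 346 for BHT_Q against BHT and 748 for AO2246 against BHT at an unadjusted p under 0.05), and DESeq2 called 0, 2, 1 and 1. Without a library B (CYC, BHT_Q or AO2246), edgeR called 1 gene each for IMZ against CYC, BHT_Q against BHT and AO2246 against BHT.

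The authors' own DESeq2 columns for PC12 list 4 (DG, TnBP) to 13 (BHT, BHT_Q) genes per compound at q under 0.05. Their log2 fold changes correlated with the edgeR values across genes at r = 0.949 to 0.996, genes being no independent replicates. LOC100912604 (Rnor_6.0 chromosome 3, 14588818 to 14591980) and LOC100363502 (chromosome 18, 62475574 to 62476771) were listed for 6 compounds each and Snrpg (chromosome 4, 118167267 to 118174846) for 5. All 3 stood at 0 to 0.39 counts in both controls and between 0 and 964, 1580 and 552 counts in treated libraries, of which 2, 5 and 6 also held 0. Over the 18 libraries they took only 8, 13 and 4 distinct values. In treated libraries LOC100912604 mostly held 241, 482 or 964 counts and Snrpg mostly 0, 184 or 552. LOC100363502 went with a set of 6 B libraries (AO2246, BHT, BHT_Q, DG, TDCIPP and TnBP), at 577 to 1580 counts there and 0 to 357 in the other 12 libraries, both controls among them. Between these 2 sets of PC12 libraries 347 genes differed.

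The effect of a compound was compared between NSC and SK for the 8 shared compounds. It differed for 19 genes under TDCIPP, 10 under IMZ, 6 under CYC and 1 under BHT_Q. Under IMZ, CCL2 rose in NSC from 16.2 to 49.2 CPM and stood at 29.4 against 34.6 CPM in SK, a difference of log2 1.84 ± 0.27 (adjusted p = 0.000706). ICAM1 (1.81 ± 0.29), EFEMP1 (1.40 ± 0.26) and NEFM (0.90 ± 0.18) differed the same way, and CCL2 (1.54 ± 0.26), DKK1 (1.33 ± 0.24) and UNC5C (0.91 ± 0.18) did under CYC. Under TDCIPP the matrix protease MMP2 (0.80 ± 0.14), LMCD1 (1.01 ± 0.16), BMP7 (0.72 ± 0.13) and HERPUD1 (0.59 ± 0.12) had higher effects in NSC, and CHRNA3 (−1.37 ± 0.30) a lower one. For AO2246, BHT, DG and TnBP edgeR found 0 such genes, with 915, 4119, 635 and 555 at an unadjusted p under 0.05 and 10, 957, 0 and 0 by DESeq2. AO2246 had 3 with the library set as a term, 2 without SK AO2246 B and 1 without SK BHT B. Of the 19 TDCIPP genes, 2 to 10 stayed past the threshold when a library of these groups was left out, of the 10 for IMZ 1 to 10, and of the 6 for CYC 0 to 4. The BHT_Q gene, PAWR (−2.17 ± 0.34), was lost without SK BHT_Q B or either SK control, and DESeq2 did not call it. Without SK BHT B the counts were 84 for TDCIPP, 69 for IMZ and 11 for CYC, and without SK BHT A 7054 for BHT.

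**Figure D3:**
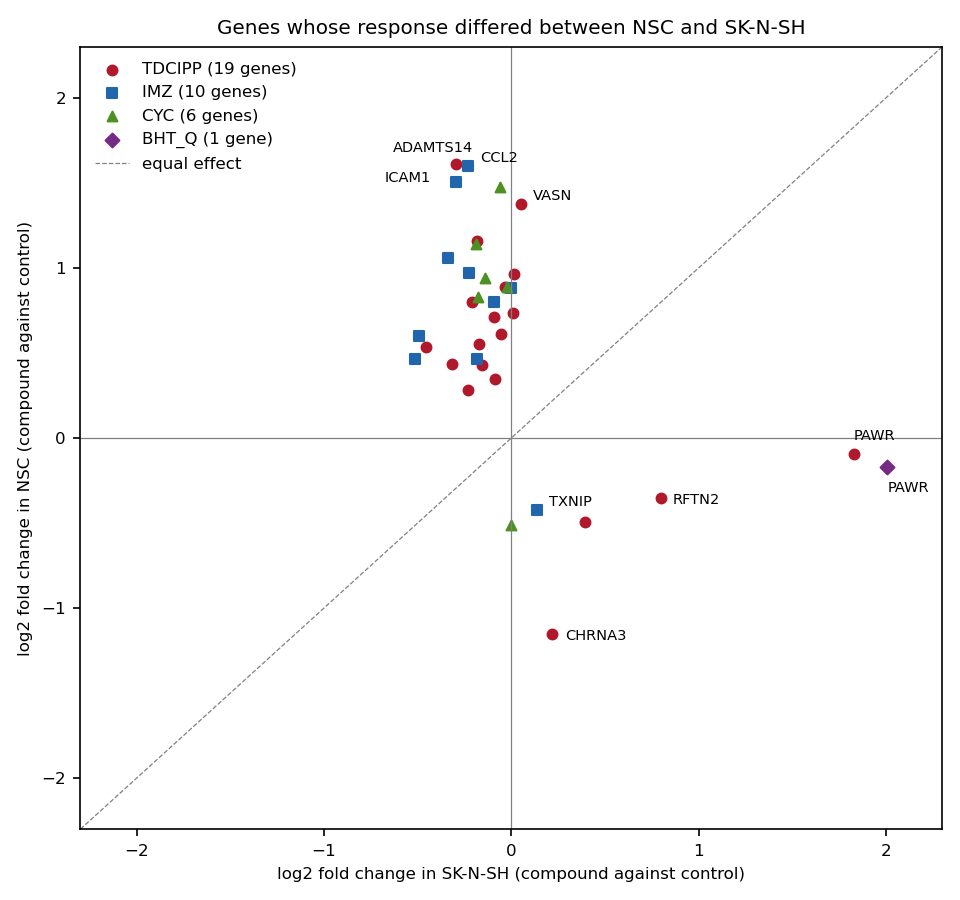
Log2 fold change in NSC (vertical axis) against that in SK (horizontal axis) for the 36 calls whose effect differed between the models, coloured by compound, with a dashed line of equal effects. The genes were picked for this difference, and most lie above the line and near 0 in SK.

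With both libraries of each group, no test found fold changes of the same compound more alike between models than those of different compounds. The mean correlation across genes was −0.04 for NSC and SK (exact permutation p = 0.448, adjusted p = 0.554), −0.01 for NSC and PC12 (exact p = 0.554, adjusted p = 0.554) and 0.02 for SK and PC12 (exact p = 0.0692, adjusted p = 0.208), one-sided over 40320 pairings. The last moved with the libraries used, at 0.05 without replicate A of every group and −0.02 without replicate B. In the full data BHT had r = 0.17 between SK and PC12, and the other compounds ran from −0.04 to 0.03. Without replicate A the SK value of BHT rests on BHT B, the library that stood apart. Within NSC, the mean r between compounds of 1 chemical class was positive only for the neonicotinoids, whose A libraries were all in 1 library set. It was 0.07 for these, −0.0064 for antioxidants and −0.0029 for organophosphate esters. Compounds of 1 class resembled each other more than those of other classes there, by a difference in r of 0.08 (permutation p = 3e-05, adjusted p = 9e-05). Within the 3 library sets of NSC it was 0.07, 0.01 and 0.07 (permutation p = 0.0571, 0.0897 and 2e-05), and the first of these sets held only neonicotinoids and organophosphate esters, both at 1 µM. In PC12 it was 0.13 (exact p = 0.00476, adjusted p = 0.00714), −0.01 without replicate B, 0.20 without replicate A and 0.06 within the set of 6 libraries (exact p = 0.133). Of the classes in PC12 only the neonicotinoids, the single pair IMZ and CYC, had a positive mean r (0.17, with −0.07 for antioxidants and −0.13 for organophosphate esters). These 2 were also the only compounds there with both libraries in the other set, so class and library set cannot be told apart. In SK it was 0.04 (exact p = 0.229, adjusted p = 0.229). Antioxidants were given at 100 nM and the other classes at 1 µM, so for the antioxidants class and dose cannot be told apart.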

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

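Of the tests in this part, the following were chosen after the result was seen: the library set as a term, the effect of DTBP, the cause common to both libraries, squamous or airway epithelium, and the effect of the exposures. For 2 of those written earlier, related values had been looked at first, namely a correlation of IMZ and CYC without control libraries and the direction of short and long genes in the libraries that stood apart.

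The effect of a compound differed between NSC and SK, tested as a difference of effects in 1 edgeR model, for 19 genes under TDCIPP, 10 under IMZ, 6 under CYC and 1 under BHT_Q. The last was PAWR, at a log2 effect in NSC minus SK of −2.17. Under CYC the differences were 1.54 for CCL2, 1.33 for DKK1, 1.08 for ARHGAP26, 1.00 for NEFM, 0.91 for UNC5C and −0.51 for TXNIP. Under IMZ they were 1.84 for CCL2, 1.81 for ICAM1, 1.40 for EFEMP1, 1.20 for DKK1, 1.10 for CDC42EP1, 0.98 for MATN2, 0.90 for NEFM, 0.89 for UNC5C, 0.65 for FBLIM1 and −0.56 for TXNIP. Under TDCIPP they were −1.93 for PAWR, 1.91 for ADAMTS14, −1.37 for CHRNA3, 1.34 for BTBD11, 1.32 for VASN, −1.15 for RFTN2, 1.01 for LMCD1, 0.99 for MXRA8, 0.95 for UNC5C and 0.92 for LPCAT2. Further TDCIPP differences were −0.89 for PGBD5, 0.80 for MMP2, 0.75 for SCARB1, 0.73 for PMP22, 0.72 for BMP7, 0.67 for IRS2, 0.59 for HERPUD1, 0.52 for P4HA1 and 0.44 for HK1. In SK on its own none of these genes passed (edgeR, adjusted p = 1 each), and PAWR stood at 1.26 CPM under BHT_Q, 1.12 CPM under TDCIPP and 0.31 CPM in the control there.

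These differences rested on few libraries. Of the 19 TDCIPP genes, those still past the threshold numbered 6 without NSC control A, 8 without NSC control B, 8 and 10 without NSC TDCIPP A and B, 5 and 4 without SK control A and B, and 3 and 2 without SK TDCIPP A and B. Of the 10 IMZ genes they numbered 2 and 1 without NSC control A and B, 3 and 6 without NSC IMZ A and B, 10 and 2 without SK control A and B, and 4 and 5 without SK IMZ A and B. None of the 6 CYC genes passed without NSC control A, NSC control B, NSC CYC A, SK control B or SK CYC A, and 4, 4 and 3 did without NSC CYC B, SK control A and SK CYC B. The BHT_Q call ended without SK BHT_Q B and without either SK control. The 2 models have separate libraries and separate controls, and no test here parts the cell model from a difference between the runs of each.

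IMZ and CYC shared 231 calls in NSC (163 higher, 68 lower), where independent calls would share 5.72 and 1.32, and their log2 fold changes correlated across genes at r = 0.681. Both were measured against the same 2 control libraries. In simulations that shared only the control, r averaged 0.496 (SD 0.0188), and r over all pairs of compounds ran from 0.44 to 0.681. With no control library used, libraries of opposite letters of IMZ and CYC correlated at 0.0562, rank 24 of 190 pairs of treated groups, which did not set this pair apart. By this measure IMZ A and CYC A correlated with their own B at only 0.134 and 0.153. The pair at rank 1, BHA and TnBP (0.139), had own values of −0.0669 and −0.035. The rank therefore cannot part a common effect from the shared control. Against the mean of the other treated groups, which also uses no control library but keeps same-letter libraries together, they correlated at r = 0.297, the highest of the pairs compared. The library set does not cancel there. Pairs with A libraries in the same set as these reached 0.215 (ACE and IMZ) and 0.18 (ACE and CYC). Across sets IMZ and TPHP had −0.251, though DTBP and IMZ had 0.0494. This value therefore cannot part likeness of the 2 compounds from the library set. Given the simulated r of 0.496, part of the overlap may come from the shared control libraries. For the library set nothing was decided. The control, IMZ and CYC each have A in 1 set and B in another, so a difference between sets cancels in their contrasts with the control. A set term then changes their spread and counts of calls (1084 for IMZ, 538 for CYC), and 231 of 231 genes kept their call for both. A common effect of the 2 compounds, both listed with the neonicotinoids, stays open and untested.

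DTBP B in NSC and BHT B in SK stood apart. DTBP B was set against the mean of the other NSC B libraries, its library set, with an SD over genes of 0.333. BHT B was set against the mean of all other 17 SK libraries, with an SD of 0.7. The 2 references are unlike, and the deviations below use them too. Ribosomal protein genes were higher in both (24 of 24 members each, by median log2 0.28 and 1.22), as were oxidative phosphorylation genes (20 of 20 each, 0.27 and 1.40). Across genes the deviation fell with transcript length, at Spearman's rho −0.37 in DTBP B and −0.394 in BHT B. With the length trend removed, 416 of the 523 genes called for DTBP kept their call, and the SD of BHT B was 0.654, above the highest of the other 17 SK libraries (0.322), so the trend was not the whole of either pattern. An effect of DTBP itself on both of its libraries stays open, since the values disagree. Without DTBP B 3 genes were called, where the lowest count of TDCIPP, IMZ and CYC without their library B was 145, yet DTBP A correlated with its own B at 0.163, rank 1 of 21 groups. The deviations of the 2 libraries correlated across genes at r = 0.463, above the 0.21 of the highest of the other 755 pairs of 1 NSC and 1 SK library. A technical cause common to both, such as RNA quality or library preparation, is a candidate explanation, and the deposited values do not name it. An effect of each exposure in 1 library alone stays open, as untested.

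In NSC, 8 libraries (the A libraries of the control, ACE, CYC, IMI, IMZ, TCEP, TEP and TnBP) held transcripts of other tissues, with median counts of 36.1 for KRT13, 33.1 for SERPINA1 and 81.5 for ALB. An effect of the exposures was argued against, as the control library among them held 112.6% of the median of the 7 exposed ones. For RNA or reads from another sample, written as needing at least 2 of 5 marker lists at 10 times or more in summed counts of genes not looked at before, 1 list reached it. That bound was too strict for a source with a single tissue, which would raise 1 list. Mean ratios were 52.4 for squamous or airway epithelium, 2 for pancreas, 1.38 for liver, 1.14 for red cells and 1.13 for muscle. The epithelial genes summed to at least 43.6 counts in each of the 8 libraries and at most 8 in the other 34. RNA or reads of squamous or airway epithelium is therefore a candidate source of these genes, as a hypothesis found in the same data, and how it would have entered is open. Whether it would bring ALB and SERPINA1, here in the liver list, was not tested. The whole liver list had a median of 361 counts in the 8 libraries and 201.5 in the other 34, so their source stays open.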

How the results depend on the processing

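Settings chosen after the data were seen were the library set as a term, the mean of the other treated groups as reference, the transcript length trend, the 8 libraries left out together, DTBP B and BHT B left out of every comparison, and each compound's own libraries left out for gene lists. In each pair of numbers below, the value under the setting comes first and the reported value follows in parentheses. Where the setting itself does not show why a value moved, the cause was not tested.

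DESeq2's size factors left all 74 counts within 1.5 times the reported ones, and of 219, 24 and 22 list calls in NSC, SK and PC12 they kept 219, 23 and 22. Spearman correlations and the higher-expressed genes kept all 6 results across models and classes. Without the filter on low counts 70 of 74 counts stayed, and more genes were tested. For NSC the counts became TCEP 2 (1) and TnBP 2 (1). Those of PC12 became TDCIPP against TnBP 1 (0) and the test over all groups 1 (0). Of the list calls 214 of 219 in NSC, 19 of 24 in SK and 20 of 22 in PC12 stayed.

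With a replicate block, a term for the letters A and B, 54 counts stayed and 26 moved. By the rule set for it, a correlation over 0.1 between every 2 groups, the letters do not pair libraries, but in NSC 178 of 210 pairs of groups passed it and 4067 of 14954 genes differed between A and B, and the first principal component parted every A from every B library. In NSC the block gave ACE 53 (17), AO168 143 (49), AO2246 76 (10), DG 6 (0), DTBP 1407 (523), IMZ 950 (592), TCEP 9 (1), TDCIPP 958 (637) and TPHP 76 (37). Blocked counts in NSC were also TnBP 8 (1), IMZ against IMI 5 (0), CYC against IMI 40 (10), TCEP against TDCIPP 226 (116), TDCIPP against TnBP 326 (190), AO2246 against BHT 18 (7) and the test over all groups 754 (340). In PC12 it gave AO2246 1 (0), BHT 1 (0), BHT_Q 1 (0), DG 1 (0), TDCIPP 1 (0), TnBP 2 (0) and the test over all groups 2 (0). For differences of effect between NSC and SK it gave BHT 855 (0), IMZ 30 (10) and TDCIPP 29 (19). It kept the named genes (124 of 124), the genes whose effect differed between models (36 of 36) and 216 of 219 list calls in NSC.

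With the library set as a term 58 counts stayed and 22 moved. For NSC the set term gave ACE 88 (17), AO168 194 (49), AO2246 139 (10), BHT_COOH 1 (0), CYC 538 (317), DG 24 (0), DTBP 1402 (523), IMI 17 (1) and IMZ 1084 (592). Further counts in NSC were TCEP 34 (1), TPHP 65 (37), TnBP 20 (1), IMZ against IMI 27 (0), CYC against IMI 96 (10), TCEP against TDCIPP 184 (116), AO2246 against BHT 23 (7) and the test over all groups 924 (340). As for differences of effect between NSC and SK, it gave AO2246 3 (0), BHT_Q 0 (1), CYC 10 (6), IMZ 55 (10) and TDCIPP 31 (19). It kept 115 of 124 named genes, 32 of 36 genes that differed between models and 183 of 219 list calls in NSC.

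Against the mean of the other treated groups, which uses no control library, 27 counts stayed and 12 moved. For NSC the values were ACE 1 (17), AO168 1 (49), AO2246 1 (10), CYC 83 (317), DTBP 811 (523), IMI 0 (1), IMZ 34 (592), TPHP 7 (37) and TnBP 0 (1). Gene lists numbered 120 (219) in NSC and 14 (22) in PC12, and BHT in SK had 2509 genes (0). This asks another question, since an effect common to all compounds cancels, while in NSC a difference between library sets does not. Camera with an estimated correlation called 0 lists in NSC (219), 0 in SK (24) and 0 in PC12 (22), where 258 NSC list tests had an unadjusted camera p under 0.05, and fry called 49, 0 and 9.

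DESeq2 as the whole tool kept 30 counts within 1.5 times and moved 41. In NSC it called ACE 70 (17), AO168 108 (49), AO2246 61 (10), BHT_Q 1 (0), DG 3 (0), DTBP 802 (523), IMI 16 (1), TCEP 38 (1) and TEP 2 (0). DESeq2 counts in NSC were TPHP 64 (37), TnBP 20 (1), IMZ against IMI 12 (0), CYC against IMI 41 (10), AO2246 against BHT 14 (7) and the test over all groups 980 (340). In SK it called AO2246 2 (0), BHT 155 (0), BHT_Q 3 (0), CYC 1 (0), DG 2 (0), TDCIPP 1 (0), TnBP 2 (0), BHT_Q against BHT 108 (0) and AO2246 against BHT 2977 (0). The DESeq2 test over all groups gave 30 (0) in SK and 23 (0) in PC12. In PC12 it called AO2246 2 (0), BHT 3 (0), CYC 2 (0), DG 1 (0), IMZ 2 (0), TDCIPP 3 (0), TDCIPP against TnBP 2 (0), BHT_Q against BHT 1 (0) and AO2246 against BHT 1 (0). Differences of effect between NSC and SK by DESeq2 were AO2246 10 (0), BHT 957 (0), BHT_Q 0 (1), CYC 22 (6), IMZ 78 (10) and TDCIPP 71 (19). It kept 111 of the 113 named genes it gave a value for and 35 of 36 genes that differed between models.

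A fit to the 2 groups of a comparison alone has 2 residual degrees of freedom, and 26 counts stayed while 34 moved. In NSC these fits gave ACE 0 (17), AO2246 22 (10), BHT_CHO 1 (0), BHT_ql 6 (0), CYC 158 (317), DG 1 (0), DTBP 0 (523), IMI 2 (1) and IMZ 355 (592). Fitted alone, NSC gave TCEP 11 (1), TDCIPP 240 (637), TEP 1 (0), TPHP 19 (37), TnBP 0 (1), CYC against IMI 0 (10), TCEP against TDCIPP 47 (116), TCEP against TEP 1 (0) and TDCIPP against TnBP 10 (190). Among pairs of groups in NSC they gave BHT_ql against BHT 3 (0). In SK these fits gave CYC 2 (0), DG 3 (0), TDCIPP 6 (0) and TDCIPP against TnBP 3 (0). Fitted alone, PC12 gave AO2246 1 (0), BHT 3 (0), BHT_Q 1 (0), CYC 3 (0), DG 2 (0), TDCIPP 2 (0), TnBP 1 (0), IMZ against CYC 1 (0) and TDCIPP against TnBP 3 (0). Among pairs of groups in PC12 they gave BHT_Q against BHT 5 (0) and AO2246 against BHT 2 (0). Of 124 named genes 68 stayed past the threshold and none reversed.

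With the 8 NSC libraries that hold transcripts of other tissues left out, control A among them, 24 counts stayed and 14 fell, with fewer libraries per group. In NSC this left ACE 0 (17), AO168 1 (49), AO2246 0 (10), CYC 12 (317), DTBP 1 (523), IMZ 8 (592), TCEP 0 (1), TDCIPP 341 (637) and TPHP 1 (37). It also left TnBP 0 (1), CYC against IMI 0 (10), TCEP against TDCIPP 24 (116), TDCIPP against TnBP 39 (190) and the test over all groups 114 (340). Of 124 named genes 27 stayed past the threshold and none reversed. List calls stayed for 134 of 219, and 5 changed direction, at adjusted p = 0.216 (BHA, cytosolic ribosomal proteins), 0.291 (BHT_Q, nuclear oxidative phosphorylation), 0.694 (IMZ, nuclear oxidative phosphorylation), 0.186 (TEP, nuclear oxidative phosphorylation), 0.124 (TEP, cytosolic ribosomal proteins).

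With the trend over transcript length removed 48 counts stayed and 10 moved. In NSC the counts were AO168 94 (49), TCEP 2 (1), TnBP 7 (1) and AO2246 against BHT 1 (7). Without the trend, SK had AO2246 against BHT 1 (0). As to differences of effect between NSC and SK, they were AO2246 1 (0), BHT 1 (0), CYC 10 (6), IMZ 43 (10) and TDCIPP 44 (19). It kept 120 of 124 named genes and 35 of 36 genes that differed between models.

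Without a single library a group rests on 1 library, which is assumed to vary like the libraries of the other groups, and where several libraries give the same end of a range 1 is named. The ranges in NSC were ACE 0 (without ACE A) to 172 (without ACE B), the test over all groups 185 (without TDCIPP A) to 1061 (without DTBP A), DTBP 0 (without control A) to 3177 (without DTBP A) and IMI 0 (without control A) to 1 (without DTBP B). Others in NSC were TCEP 0 (without control A) to 1 (without DTBP B), TPHP 2 (without control A) to 51 (without DTBP B), IMZ 84 (without control B) to 777 (without DTBP B) and TDCIPP 94 (without control B) to 777 (without DTBP B). Next came TnBP 0 (without TnBP B) to 2 (without control B), AO168 0 (without AO168 A) to 63 (without DTBP B), AO2246 0 (without AO2246 A) to 9 (without DTBP B) and AO2246 against BHT 0 (without AO2246 A) to 8 (without DTBP B). NSC ranges further included CYC 23 (without CYC A) to 374 (without DTBP B), CYC against IMI 0 (without CYC A) to 13 (without DTBP B), IMZ against IMI 0 (without DTBP B) to 2 (without IMZ B) and TCEP against TDCIPP 29 (without TCEP A) to 176 (without DTBP B). The last range in NSC was TDCIPP against TnBP 48 (without TnBP A) to 258 (without DTBP B).

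In SK the ranges were AO2246 0 (without AO2246 A) to 2 (without AO2246 B), AO2246 against BHT 0 (without AO2246 A) to 8895 (without BHT A), the test over all groups 0 (without AO2246 A) to 6134 (without BHT A) and BHT 0 (without BHT B) to 8357 (without BHT A). SK ranges were also BHT_Q against BHT 0 (without BHT B) to 8260 (without BHT A), TDCIPP 0 (without control A) to 1 (without BHT B) and gene lists 13 (without control B) to 33 (without BHT B). In PC12 they were AO2246 0 (without AO2246 A) to 4 (without control B), AO2246 against BHT 0 (without AO2246 A) to 1 (without AO2246 B), the test over all groups 0 (without AO2246 A) to 1 (without BHT_Q B) and BHT 0 (without BHT A) to 2 (without control B). Next in PC12 were BHT_Q 0 (without BHT_Q A) to 3 (without control B), CYC 0 (without control A) to 7 (without control B), DG 0 (without control A) to 2 (without control B) and IMZ 0 (without control A) to 4 (without control B). PC12 ranges were also TDCIPP 0 (without control A) to 3 (without control B), TnBP 0 (without control A) to 4 (without control B), BHT_Q against BHT 0 (without BHT A) to 1 (without BHT_Q B) and IMZ against CYC 0 (without CYC A) to 1 (without CYC B). Genes whose effect differed between NSC and SK ranged by compound: CYC 0 (without NSC control A) to 11 (without SK BHT B), IMZ 1 (without NSC control B) to 69 (without SK BHT B), AO2246 0 (without NSC AO2246 A) to 2 (without SK AO2246 B) and BHT 0 (without NSC BHT A) to 7054 (without SK BHT A). Further ranges of these were TDCIPP 2 (without SK TDCIPP B) to 84 (without SK BHT B) and BHT_Q 0 (without SK BHT_Q B) to 1 (without NSC BHT_Q A). The correlation of the same compound in SK and PC12 was −0.0201 without replicate B of every group and 0.0451 without replicate A (exact permutation, adjusted p = 0.0304), and the class difference in PC12 −0.0057 and 0.2.

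No named gene changed direction without a library, and 286 of 605 such tests stayed past the threshold. Of the genes that differed between models 131 of 324 did. List calls stayed in 824 of 1082 tests in NSC, 77 of 117 in SK and 63 of 88 in PC12, and 15, 3 and 1 changed direction. Ranges of the adjusted p of these lists follow. In NSC they were DTBP, nuclear oxidative phosphorylation 3.86e-07 (without DTBP A) to 0.991 (without DTBP B), DTBP, cytosolic ribosomal proteins 2.51e-07 (without DTBP A) to 0.533 (without DTBP B) and ACE, cytosolic ribosomal proteins 4.45e-08 (without control A) to 0.996 (without control B). NSC lists also ran over BHA, cytosolic ribosomal proteins 7.88e-07 (without control B) to 0.203 (without control A), BHT, cytosolic ribosomal proteins 1.86e-06 (without control A) to 0.968 (without BHT A) and CYC, cytosolic ribosomal proteins 4.41e-06 (without control A) to 0.599 (without control B). Others were IMZ, nuclear oxidative phosphorylation 4.09e-05 (without control B) to 0.801 (without control A), TEP, nuclear oxidative phosphorylation 3.83e-06 (without control B) to 0.601 (without control A) and TnBP, cytosolic ribosomal proteins 1.38e-06 (without control B) to 0.543 (without control A). Further lists were BHT_Q, nuclear oxidative phosphorylation 3.23e-06 (without control B) to 0.876 (without BHT_Q B), TEP, cytosolic ribosomal proteins 4.22e-06 (without control B) to 0.288 (without TEP A) and TnBP, synaptic and ion channel genes 0.000211 (without TnBP A) to 0.988 (without TnBP B). The last in NSC was TBHQ, neuronal differentiation 2.74e-07 (without TBHQ B) to 0.635 (without TBHQ A). In SK they were AO2246, DNA replication 2.66e-05 (without SK AO2246 B) to 0.957 (without SK AO2246 A), TnBP, hypoxia and glycolysis 1.02e-05 (without SK control A) to 0.947 (without SK control B) and CYC, hypoxia and glycolysis 4.36e-08 (without SK CYC B) to 0.917 (without SK CYC A). In PC12 the range was BHT_Q, cytosolic ribosomal proteins 1.18e-06 (without BHT_Q B) to 0.727 (without BHT_Q A).

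As for precision, the biological coefficient of variation was 6.62% in NSC, 11.6% in SK and 10.8% in PC12. The median 95% interval of a log2 fold change was ±0.22, ±0.33 and ±0.28.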

Other observations

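The control differed from the mean of all other NSC groups for 15 genes (edgeR), 11 of them higher and 4 lower in the treated groups, and 15 of the 15 kept their call with the library set as a term. Each group was set against the mean of all others in the same way, and 5 of the 21 groups had at least as many calls, the control included: DTBP 922, TDCIPP 829, CYC 109, IMZ 82 and the control 15. This comparison was chosen after the recurrent genes had been seen. No explanation of it is put forward.

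The 3 library sets of NSC, read from the counts of KRT13 and RPSAP58, were 8 A libraries, the other 13 A libraries and the 21 B libraries, and 3831 genes differed between them. All 4 neonicotinoids and 3 of the 5 organophosphate esters had their A library in the first set, and no antioxidant did.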
